A study of Mus musculus with 24 samples.

How the data were processed

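Total RNA of mouse liver, prepared with RNeasy columns per the labels' protocols, was converted to Cy5 cRNA with the Quick Amp kit and hybridised together with Cy3 universal mouse reference RNA. There were 24 arrays, 1 per library, in 6 groups of 4 made by genotype (WT or GCGR KO) and age (E18.5, P2.5 or P7.5), as the labels give them, with 0 columns from other samples. The dyes were not exchanged on any array. Livers at P19 and 3 months, which the series description names, were not analysed here.

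Per the file headers, the scanner files hold median pixel intensity for each spot and its local background in both channels, without normalization. They were made with Feature Extraction 11.5.1.1 for WT arrays and 11.0.1.1 for KO arrays, and the submitters' processing notes name Feature Extraction 11. The same files hold a log10 ratio of Cy5 over Cy3 that, per the file headers, Feature Extraction computed after its own background and dye normalization. The deposited series matrix holds log2 values with column medians between -0.00119 and 0.0116. Its scale and direction are not stated by the authors, and it correlated closely with the log2 ratio computed here. The design had named mean signals, which the files do not hold, so medians were used.

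Log2 ratios of Cy5 over Cy3 were computed with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8). Spots marked in the files as non-uniform or as population outliers in either channel were left out before the background was fitted, because very bright local background on some WT arrays upset that fit. Background was corrected by normexp with an offset of 50, dye bias was removed by loess within each array with control spots at weight 0, and no normalization between arrays was applied. Of 39429 probes 26581 carried 1 gene symbol, for 20144 genes, and 12848 carried none and were not analysed here. Each gene was represented by its brightest probe. A gene was tested when that probe was well above background in Cy5 on at least 4 of the 24 arrays, which left 17266 genes with 184 missing values. The number of arrays and the signal over background limit the precision.

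Each gene was fitted in limma with a mean for each of the 6 groups and moderated variances (eBayes). KO was compared with WT at each of the 3 ages, successive ages were compared within each genotype, and the change of the KO-WT difference between successive ages was tested as an interaction. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Of 35 gene lists fixed before the data were examined, 34 were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The list of sex-linked genes was not tested, since the labels give no sex. Lists that passed are given in the text with the lists closest to glucagon action, whether or not those passed.

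The genes named were chosen by a rule fixed with the design. Gcgr is named in every comparison. For KO against WT the rule takes the 10 largest rises and 10 largest falls among genes that passed, whose 4 KO and 4 WT values did not overlap and whose probe was well above background on at least 3 of the 4 arrays of the higher group. For ages and interactions it takes the 5 largest in each direction, without the overlap criterion for interactions. Clone, accession and predicted gene names and the sex-linked list were skipped. From each list described, up to 4 members with the lowest adjusted p were added (up to 2 for ages and interactions). Some genes that the rule takes are not reported here. The same rule was applied at P7.5 without the library labelled P7.5 KO replicate 2, a choice made after Gcgr had been read in it.

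Arrays lay on 9 slides. Slides with WT and KO arrays were separate, so that slide was tried as a random block (correlation within slides 0.0799) and, for the 12 WT arrays, as a fixed block. Other alternatives were no background subtraction, the Feature Extraction log ratio, the series matrix, Cy5 alone with quantile normalization, no filter and a stricter filter (12 arrays), the mean of all probes, array weights, fits on the compared groups alone, the replicate number as a block, and omission of each library in turn. Quantile normalization of the average intensities between arrays was also run, but it leaves the log ratios unchanged and so could not alter any result. Background fitted on all spots, and omission of both libraries in doubt together, were chosen after seeing the data.

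The scripts' calls were tested on simulated data for KO against WT at P7.5 with 17266 genes. Of 50 genes changed by 0.5 on the log2 scale 62% were recovered, of 50 changed by 1 94%, of 50 changed by 2 100% and of 47 changed by 4 100%. The amino acid catabolism list was shifted by 0.5 in the same simulation. Among all calls, those of this list included, 10 were unchanged genes (5.03%).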

Results

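Liver RNA from wildtype (WT) mice and from mice lacking the glucagon receptor (GCGR KO) was profiled on dual-colour Agilent arrays before and after birth, at E18.5, P2.5 and P7.5. Each of the 6 groups held 4 libraries, 24 in all. Every library was read in Cy5 against the same kind of pooled mouse reference RNA in Cy3, so that each value is a log2 ratio of liver over reference. Between 22668 and 31882 of 39429 probes were well above background in Cy5, and 17266 genes with a symbol were tested. Libraries of the same group correlated across genes between 0.942 and 0.995. Some pairs of different groups lay within that range, such as P7.5 WT replicate 4 with P7.5 KO replicate 2 (0.975) and P2.5 WT replicate 1 with P2.5 KO replicate 4 (0.964). The number of arrays limits the precision. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between libraries. WT and KO libraries lay on separate slides, scanned on different days with different versions of the scanner software, so that genotype and slide set cannot be told apart within an age.

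Gcgr itself, which encodes the glucagon receptor, was read in every library. In WT liver its log2 ratio over the reference was 5.07, 5.74, 5.28 and 4.87 at E18.5, 5.51, 5.75, 6.26 and 5.74 at P2.5, and 5.50, 5.61, 5.65 and 5.65 at P7.5. In KO liver it was 0.00, -0.01, 0.13 and 0.19 at E18.5 and 0.17, 0.38, 0.37 and 0.19 at P2.5. At P7.5 the KO libraries read 0.00, 5.02, 0.26 and -0.01. The library labelled P7.5 KO replicate 2 thus carried Gcgr at 66.7% of the P7.5 WT level, against its label, and P7.5 KO values are given with it and, where it matters, without it. Gcgr was 35.8-fold lower in KO at E18.5 (limma, log2 change -5.16 ± 0.66 (SE, n = 4 against 4), adjusted p = 1.53e-05), 46.5-fold lower at P2.5 (-5.54 ± 0.66, adjusted p = 1.04e-05) and 19.5-fold lower at P7.5 (-4.29 ± 0.66, adjusted p = 6.43e-05). Without the library labelled P7.5 KO replicate 2 the P7.5 change was -5.52 ± 0.16 (adjusted p = 1.37e-15). Between ages Gcgr did not pass the threshold in WT (0.58, adjusted p = 0.563, from E18.5 to P2.5 and -0.21, adjusted p = 0.833, from P2.5 to P7.5). The spread of Gcgr was estimated over all arrays, so the library labelled P7.5 KO replicate 2 widened it in these comparisons too. A change of Gcgr with age in WT is therefore not excluded.

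**Figure D1:**
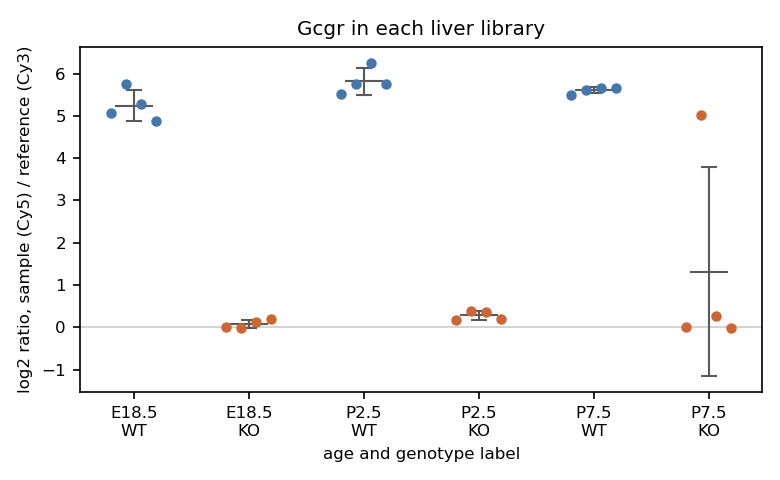
Log2 ratio of Gcgr over the reference (y axis) in each of the 24 libraries (points), by age and genotype (x axis), with bars for the mean ± SD of the 4 libraries of a group. All WT libraries lie at or above 4.87, 11 KO libraries lie at or below 0.38, and the library labelled P7.5 KO replicate 2 lies at 5.02.

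KO and WT livers before birth were compared at E18.5, where loss of the receptor and slide set cannot be told apart. KO livers had more RNA for Stc1, the secreted hormone stanniocalcin, and for Cbfa2t3, a corepressor of transcription in blood cells. They also had more for the matrix protein gene Comp. Some genes of glycogen metabolism rose, such as the branching enzyme gene Gbe1 and Pgm1. So did the sugar phosphate enzymes Gpi1 and Aldoa, the lactate dehydrogenases Ldha and Ldhd, and cytosolic malate dehydrogenase Mdh1. The acyl-CoA dehydrogenases Acadvl and Acads and the amino acid transporters Slc7a2 and Slc7a8 rose as well, as did Sik1 and Ppargc1a, which are targets of cAMP signalling in hepatocytes, although Ppargc1a turned to -0.34 when Cy5 was read without the reference. The adhesion molecule gene Ceacam2, the cyclin gene Ccny, the eosinophil ribonuclease gene Ear6 and several small structured RNAs fell.

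Stc1 rose by 2.94 ± 0.52 on the log2 scale (SE, n = 4 against 4, limma adjusted p = 0.000342) and Cbfa2t3 by 2.66 ± 0.40 (adjusted p = 7.15e-05). Rnf150 rose by 1.99, Ptchd1 by 1.98 and the olfactory receptor gene Olfr1370 by 1.85. The aspartyl-tRNA synthetase gene Dars rose by 1.73, Cntn4 by 1.59 and Comp by 1.54. The hexokinase family gene Hkdc1 rose by 1.65, but changed by -0.19 in the log ratios of Feature Extraction. By the naming rule the 4 KO and 4 WT values of each of these genes did not overlap. Gbe1 rose by 0.89 ± 0.17 (adjusted p = 0.000694). Pgm1 rose by 0.68, Gpi1 by 0.88, Aldoa by 0.63, Ldha by 1.16, Ldhd by 0.77 and Mdh1 by 0.71. Sik1 rose by 0.97 ± 0.20 (adjusted p = 0.00148) and Ppargc1a by 1.04 ± 0.32 (adjusted p = 0.0189). Acadvl and Acads rose by 0.68 and 0.67, and Slc7a8 and Slc7a2 by 0.91 and 0.82. The oocyte homeobox gene Obox1 fell by 2.56 ± 0.32 (adjusted p = 1.24e-05) and Ceacam2 by 1.99 ± 0.18 (adjusted p = 3.98e-07). Ccny fell by 1.83, Lsm14b by 1.74 and Ear6 by 1.55. The U1 and U2 RNA genes Rnu1b6 and Rnu2-10 fell by 1.98 and 1.56, and the ribonuclease P RNA genes Rprl2 and Rpph1 by 1.65 and 1.55. At P7.5 the library labelled P7.5 KO replicate 2, on a KO slide with Gcgr present, was placed between WT (0) and the other KO libraries (1). It lay at 0.892 for Stc1, 1.03 for Cbfa2t3, 0.742 for Ceacam2 and 0.846 for Ccny. For Gbe1, Pgm1 and Ldha it lay at 0.361, 0.231 and 0.147. This library alone does not decide which of these changes follow Gcgr.

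In all, 4680 of 17266 genes passed an adjusted p of 0.05 at E18.5, 2716 higher and 1964 lower in KO, and 198 of them changed at least 2-fold, 138 higher and 60 lower. With the log ratios of Feature Extraction 1106 changed at least 2-fold and the split was 2119 higher and 3106 lower, so that the balance depends on the processing. With slide as a random block 3945 genes passed. Of the glycogen metabolism list 6 of 16 genes rose and 1 fell (7 and 2 adjusted over the list alone), of glycolysis 7 of 17 rose and 1 fell, and of fatty acid oxidation and ketogenesis 7 of 23 rose and 1 fell. Among gluconeogenesis genes 5 of 12 rose and 3 fell, while 4 of 48 amino acid catabolism genes rose and 1 fell, and 1 of 8 urea cycle genes rose. Cytosolic ribosomal protein genes split into 12 of 40 that fell and 3 that rose, with Rps2 at -0.61 and Rpl15 at -0.51, and Rpl4 at 0.51 (-0.079 in Cy5 alone). By camera none of the 34 lists passed as a whole at E18.5. The lowest adjusted p was 0.254, shared by glycogen metabolism and ribosomal proteins, and 4 lists had an unadjusted p under 0.05. By fry in limma, which asks whether a list moves one way without comparing it with other genes, 2 of the lists passed, glycogen metabolism among them.

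**Figure D2:**
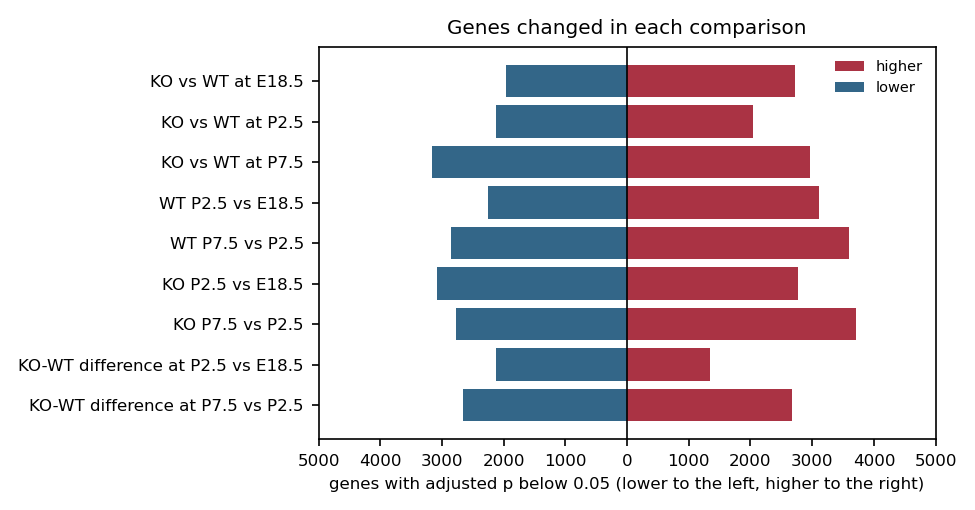
Number of genes past an adjusted p of 0.05 (x axis) in each comparison (y axis), drawn to the right where higher and to the left where lower. KO and WT differed at 4680 genes at E18.5, 4166 at P2.5 and 6126 at P7.5.

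The comparison at P2.5 covers the days after birth. The eosinophil granule genes Prg2, Prg3, Epx and Ear6 were higher in KO. They encode major basic protein, its relative, eosinophil peroxidase and a ribonuclease. Genes for proteins that hepatocytes secrete into plasma fell, among them the complement gene C3 and the inhibitor heavy chain gene Itih3. Fgg and Rbp4 fell too but turned to 0.22 and 0.18 in Cy5 alone. Fetal liver genes fell as well, with Afp for alpha-fetoprotein and Igf2, although Igf2 changed by 0.054 in the log ratios of Feature Extraction. Genes of drug metabolism (Gstp1, Fmo1, Cyp2e1), of the respiratory chain (Cyc1, Uqcrc2), of amino acid breakdown (Hibadh, Glud1) and of cell division (Ube2c, Ccna2) were lower in KO. So were the gluconeogenic gene Fbp1 and the insulin receptor substrate gene Irs2.

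Prg2 rose by 2.85 ± 0.18 on the log2 scale (SE, n = 4 against 4, limma adjusted p = 1.3e-09) and Ear6 by 2.07 ± 0.33 (adjusted p = 0.000186). Epx rose by 1.92 ± 0.33 (adjusted p = 0.000345) and Prg3 by 1.74 ± 0.29 (adjusted p = 0.000251). The Prg2 log2 ratios of the P2.5 WT libraries were 0.86, 1.62, 0.86 and 0.35. Grrp1 rose by 1.61, Gdpd2 by 1.42, and Rpgrip1 by 1.41. The glycoprotein hormone gene Gpha2 rose by 1.39, the ephrin receptor gene Ephb6 by 1.32 and the urea transporter gene Slc14a2 by 1.31. Sik1 rose by 0.90 (adjusted p = 0.00339) and Hmga2, a fetal liver gene that rose while some others of its list fell, by 0.78. Ceacam2 fell by 3.17 ± 0.18 (adjusted p = 5.87e-10) and the sulfate transporter gene Slc26a1 by 2.44 ± 0.18 (adjusted p = 7.71e-09). Ccny fell by 2.22 and the calcium pump gene Atp2b2 by 2.10. The endothelial phosphatase gene Ptprb fell by 2.01, Slfn9 by 1.99, Adap2 by 1.64 and the fibronectin gene Fn1 by 1.61 ± 0.32 (adjusted p = 0.00107). C3 fell by 1.67 ± 0.29 (adjusted p = 0.000375), Itih3 by 0.89 and Afp by 1.09 ± 0.14 (adjusted p = 1.74e-05). Fgg changed by -0.81, Rbp4 by -0.74 and Igf2 by -1.27. Gstp1 fell by 1.06, Fmo1 by 0.90, Cyp2e1 by 0.65, Irs2 by 1.05 and Fbp1 by 0.71 (adjusted p = 0.000355). Cyc1 fell by 0.66, Uqcrc2 by 0.44, Hibadh by 0.49, Glud1 by 0.49, Ube2c by 0.56 and Ccna2 by 0.49.

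At P2.5, 4166 genes passed, 2038 higher and 2128 lower in KO, and 157 changed at least 2-fold, 52 higher and 105 lower. With the log ratios of Feature Extraction 1011 changed at least 2-fold. With slide as a random block 3810 passed, and 1694 when only the P2.5 arrays were fitted. Of the hepatocyte secreted proteins 16 of 28 genes fell and 0 rose, with the same count adjusted over the list alone (median log2 change -0.54, camera adjusted p = 8.48e-07, and adjusted p = 0.764 with an estimated correlation). Oxidative phosphorylation had 10 of 31 genes lower and 0 higher (10 adjusted over the list alone, camera adjusted p = 0.0163, and adjusted p = 0.764 with an estimated correlation). In the cell cycle list 10 of 36 genes fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.0163, and adjusted p = 0.773 with an estimated correlation). Amino acid catabolism had 10 of 48 genes lower and 0 higher (9 adjusted over the list alone, camera adjusted p = 0.0195, and adjusted p = 0.764 with an estimated correlation). Of the fetal liver genes 7 of 18 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.0195, and adjusted p = 0.696 with an estimated correlation). Of the drug metabolizing enzymes 7 of 25 fell and 0 rose (8 adjusted over the list alone, camera adjusted p = 0.0396, and adjusted p = 0.764 with an estimated correlation). These 6 lists were all lower in KO. With the log ratios of Feature Extraction 1 list passed, and with an estimated correlation 0. Gluconeogenesis did not pass as a list (1 of 12 genes fell, camera adjusted p = 0.205), nor did the urea cycle (2 of 8 fell, adjusted p = 0.200), the cAMP response genes (3 of 15 rose and 1 fell, adjusted p = 0.154) or the granulocyte and monocyte list (4 of 18 rose and 1 fell, adjusted p = 0.306).

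At P7.5 the differences covered matrix-forming cells, amino acid breakdown and the acute phase. Genes typical of stellate cells and fibroblasts were higher in KO, with Col1a1, the collagen-binding proteoglycan gene Dcn, the lectin gene Colec10 and the growth factor receptor gene Pdgfra. Timp2, an inhibitor of matrix proteases, rose with them. The endothelial genes Lyve1 and Oit3 rose while the receptor gene Kdr fell. Genes that break down amino acids fell, among them Sds (serine dehydratase), Sdsl, Gls2 (liver glutaminase) and Gnmt, together with the urea cycle genes Ass1 and Slc25a15. The metallothionein genes Mt1 and Mt2, the serum amyloid genes Saa1, Saa2 and Saa3 and the orosomucoid genes Orm1 and Orm2 fell. The glycogen gene Gbe1 rose, as did Stc1. The cAMP-linked genes split, with Ppargc1a and Irs2 higher and Crem and Pde4b lower. Several of these changes were larger without the library labelled P7.5 KO replicate 2, whose values lay nearer to those of WT.

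**Figure D3:**
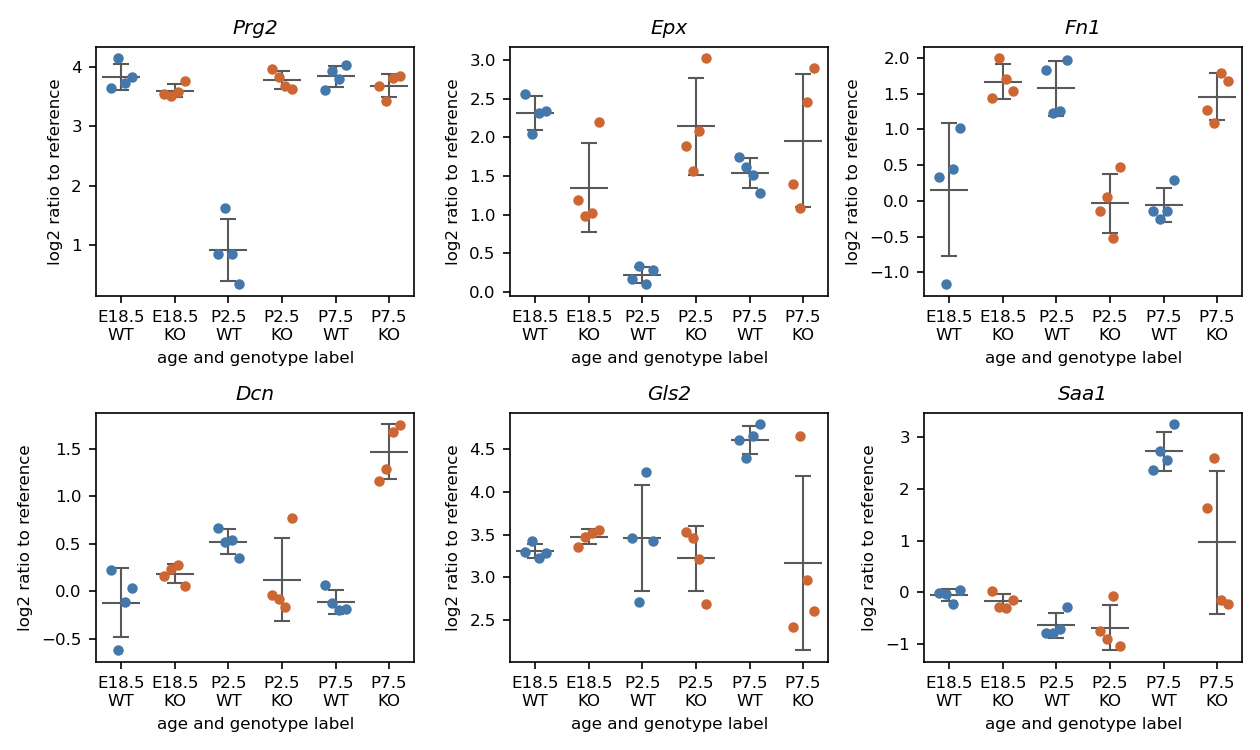
Log2 ratio over the reference (y axis) of Prg2, Epx, Fn1, Dcn, Gls2 and Saa1 in each library (points), by age and genotype (x axis), with bars for the mean ± SD of the 4 libraries of a group. Prg2 is low in the P2.5 WT libraries alone, Dcn is higher in KO at P7.5, and Gls2 is lower in 3 of the 4 libraries labelled P7.5 KO.

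Timp2 rose by 2.88 ± 0.22 on the log2 scale (SE, n = 4 against 4, limma adjusted p = 2.14e-08), the translation repressor gene Eif4ebp2 by 2.86 ± 0.26 (adjusted p = 1.29e-07), Stc1 by 2.89 and Rnf150 by 2.48. The transcription factor gene Jun rose by 2.23 ± 0.16 (adjusted p = 5.05e-09) and the Wnt coreceptor gene Lrp6 by 2.17. Efna5 rose by 2.06, Zmiz1 by 2.03 and the sterol carrier gene Stard4 by 1.94. Col1a1 rose by 2.05 ± 0.37 (adjusted p = 0.000239) and Dcn by 1.58 ± 0.18 (adjusted p = 2.64e-06). Colec10 rose by 1.57, Lyve1 by 1.45, Oit3 by 0.87 and Pdgfra by 0.60, while Kdr fell by 0.71. Gbe1 rose by 0.75 ± 0.17 (adjusted p = 0.00202), Ppargc1a by 1.28 and Irs2 by 0.94. Crem fell by 0.90 and Pde4b by 0.58. Gls2 fell by 1.45 ± 0.34 (adjusted p = 0.00224), Sdsl by 0.95, Gnmt by 0.94, Ass1 by 0.99 and Slc25a15 by 0.72. The small RNA genes Rnu1b6, Rprl2, Rpph1, Rmrp and Rnu3b1 fell by 2.55, 1.90, 1.87, 1.52 and 1.49. Mmd2 fell by 2.41, Sfi1 by 1.66, Dnm1 by 1.51 and the imprinted noncoding gene Mirg by 1.48. The platelet genes Gp9 and Pf4 fell by 1.1 and 1.01 and the T cell gene Cd3d by 1.05. The pentraxin gene Apcs fell by 0.61, and the respiratory chain genes Cox4i1 and Uqcrq by 0.68 and 0.63. Rps2 fell by 0.52 and Rpl13 by 0.46. Fgg at -0.88, Fgl1 at -0.83 and Rbp4 at -0.49 turned to 0.080, 0.20 and 0.043 in Cy5 alone.

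The library labelled P7.5 KO replicate 2 decided the size of a further group of changes. Sds read 1.52, 4.78, 2.48 and 2.13 in the libraries labelled P7.5 KO and between 4.39 and 5.16 in WT, which gave a change of -2.07 ± 0.50 (adjusted p = 0.00304). It became -2.76 ± 0.39 (adjusted p = 2.41e-05) without that library. Mt2 went from -3.63 (adjusted p = 0.00236) to -4.88 (adjusted p = 6.09e-06). Mt1 went from -2.46 to -3.27, Orm2 from -2.44 to -3.50, and Orm1 from -2.09 to -3.01. Saa2 went from -2.48 to -3.28, Saa1 from -1.77 to -2.31 and Saa3 from -1.35 to -1.68. The G protein regulator gene Rgs16 went from 2.97 (adjusted p = 0.00244) to 4.12 (adjusted p = 4.14e-07) and the water channel gene Aqp4 from 1.88 to 2.34. Fgf21, which encodes a hormone made by hepatocytes, did not pass with all libraries (1.57, adjusted p = 0.099) and passed without it (2.25, adjusted p = 0.0158). Gls2 went to -1.95, Ass1 to -1.46 and Slc25a15 to -0.98.

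In all, 6126 genes passed at P7.5, 2970 higher and 3156 lower in KO, and 330 changed at least 2-fold, 234 higher and 96 lower. Without the library labelled P7.5 KO replicate 2 there were 6500, 3185 higher and 3315 lower, and 562 changed at least 2-fold, 363 higher and 199 lower. With all libraries and the log ratios of Feature Extraction 2677 genes were higher and 4133 lower, and 1402 changed at least 2-fold. With background fitted on all spots 2876 were higher and 2333 lower, so that the balance depends on the processing. With slide as a random block 5401 passed. Of the stellate cell and fibroblast list 12 of 17 genes rose and 1 fell (13 and 1 adjusted over the list alone, median 0.60, camera adjusted p = 7.7e-05, and adjusted p = 0.897 with an estimated correlation). Ribosomal protein genes had 20 of 40 lower and 2 higher (21 and 4 adjusted over the list alone, camera adjusted p = 0.000626, and adjusted p = 0.291 with an estimated correlation). Oxidative phosphorylation had 16 of 31 lower and 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 0.000733, and adjusted p = 0.897 with an estimated correlation). Amino acid catabolism had 14 of 48 lower and 0 higher (14 adjusted over the list alone, camera adjusted p = 0.00591, and adjusted p = 0.897 with an estimated correlation). Of the megakaryocyte genes 5 of 14 fell (9 adjusted over the list alone, camera adjusted p = 0.022, and adjusted p = 0.897 with an estimated correlation). Of the acute phase genes 8 of 15 fell (8 adjusted over the list alone, camera adjusted p = 0.0335, and adjusted p = 0.897 with an estimated correlation). The hepatocyte secreted proteins had 9 of 28 genes lower and 1 higher (10 and 1 adjusted over the list alone, camera adjusted p = 0.0418, and adjusted p = 0.901 with an estimated correlation), with a median of -0.23 that became 0.025 in Cy5 alone. The endothelial list had 8 of 17 genes higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0428, and adjusted p = 0.897 with an estimated correlation), with a median of 0.27 that became -0.086 in the log ratios of Feature Extraction.

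The urea cycle and the T and NK lymphoid list did not pass at P7.5 with all libraries (3 of 8 genes lower, camera adjusted p = 0.106, and 5 of 15 lower, adjusted p = 0.114). Without the library labelled P7.5 KO replicate 2 both passed, with 5 of 8 genes lower (adjusted p = 0.0064) and 8 of 15 lower (adjusted p = 0.00743), each at adjusted p = 0.563 with an estimated correlation. Amino acid catabolism went to 18 of 48 lower and 1 higher (adjusted p = 0.000307, and adjusted p = 0.628 with an estimated correlation). The stellate cell and fibroblast list then had 15 of 17 genes higher and 0 lower (adjusted p = 3.63e-06, and adjusted p = 0.509 with an estimated correlation) and the megakaryocyte list 10 of 14 lower (adjusted p = 0.000307, and adjusted p = 0.563 with an estimated correlation). Gluconeogenesis, glycogen metabolism and the cAMP response genes did not pass as lists at P7.5 with all libraries (adjusted p = 0.705, 0.325 and 0.514), with 3 of 12 genes higher and 1 lower, 5 of 16 higher and 3 lower, and 2 of 15 higher and 2 lower.

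**Figure D4:**
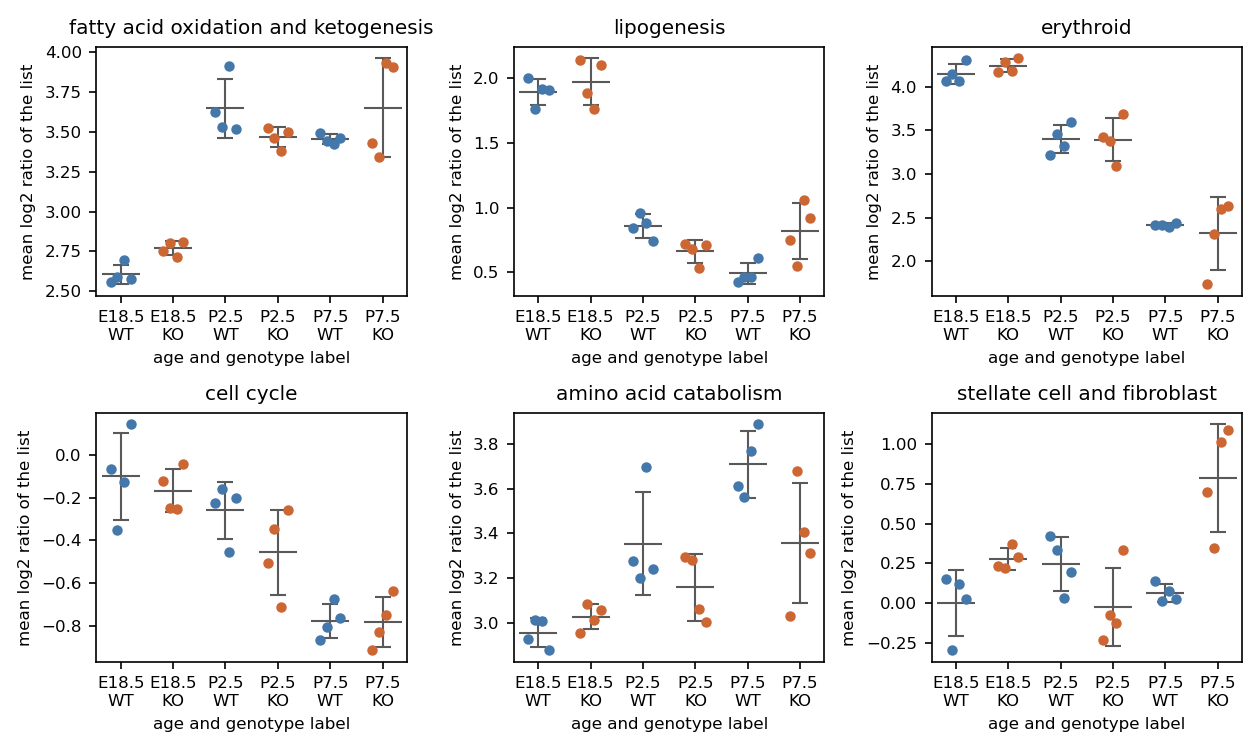
Mean log2 ratio over the reference of the genes of 6 lists (y axis: fatty acid oxidation, lipogenesis, erythroid, cell cycle, amino acid catabolism, and stellate cell and fibroblast genes) in each library (points), by age and genotype (x axis), with bars for the mean ± SD of the 4 libraries of a group. Erythroid genes fall with age in WT, and stellate cell and fibroblast genes are higher in KO at P7.5.

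The KO and WT libraries of one age are not used at another age, so that the log2 changes at the 3 ages share no libraries. The calls are not independent, since the spread of each gene was estimated over all arrays. A gene with a small spread is thus more easily called at every age. An offset between the KO and WT slides could also be shared by the ages. The numbers for independent lists below are therefore given for scale only and are not a test. At E18.5 and P7.5, 1584 genes were higher in KO at both ages against 467.2 for independent lists, 1290 were lower at both against 359 for independent lists, and 25 went from higher to lower and 7 from lower to higher. E18.5 and P2.5 shared 560 higher and 533 lower genes (320.6 and 242.1 for independent lists), and 242 went from higher to lower and 120 from lower to higher. P2.5 and P7.5 shared 416 higher and 501 lower genes (350.6 and 389 for independent lists), and 377 went from higher to lower and 434 from lower to higher. Across genes, which are not independent replicates, the changes correlated at 0.652 between E18.5 and P7.5, 0.157 between E18.5 and P2.5 and -0.00737 between P2.5 and P7.5. In all, 287 genes were higher and 348 lower in KO at all 3 ages. The P7.5 counts include the library labelled P7.5 KO replicate 2.

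Whether the genotype difference itself changed from E18.5 to P2.5 was tested as an interaction, in which a gene-wise offset between the sets of slides that stays the same at all ages cancels. Each KO slide held 1 age, so that an effect of a single KO slide cannot be told apart from an interaction. Some genes of matrix and plasma proteins moved down in KO relative to WT, namely Fn1, the basement membrane gene Nid1, Itih5, C3 and A2m. So did genes of glycogen and sugar metabolism (Phka2, Aldoa, Gapdh), fatty acid oxidation (Acadvl, Acads), amino acid breakdown (Hibadh, Mccc1) and the insulin receptor gene Insr. The eosinophil genes Prg2, Prg3, Epx and Ear6, the oocyte homeobox gene Obox1, the ribosomal protein genes Rps27 and Rps3 and the B cell genes Vpreb3 and Cd79b moved up.

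The difference changed for Fn1 by -3.12 ± 0.45 (SE, log2, n = 4 in each of the 4 groups, limma adjusted p = 0.000209), A2m by -2.79, Nid1 by -2.39, Itih5 by -2.35, the imprinted gene Plagl1 by -2.30 and C3 by -2.26. Insr changed by -1.43 ± 0.28 (adjusted p = 0.00203), Reln by -1.29 and Ecm1 by -1.23. Acadvl changed by -1.05, Acads by -0.87, Hibadh by -0.84, Gapdh by -0.82, Aldoa by -0.78, Phka2 by -0.63, and Mccc1 by -0.60. Igfbp1 and F9 changed by -1.80 and -1.41, but by 0.66 and 0.17 in Cy5 alone. Ear6 changed by 3.62, Obox1 by 3.61 and Prg2 by 3.09 ± 0.25 (adjusted p = 4.97e-07). Prg3 changed by 2.93, Epx by 2.89, Vpreb3 by 1.29, Cd79b by 1.19, Rps27 by 0.67 and Rps3 by 0.49. In all 3473 genes passed, 1346 up and 2127 down. The split was 1658 up and 1628 down with the log ratios of Feature Extraction and 1812 up and 1884 down in Cy5 alone. With slide as a random block 3119 passed. For Gcgr the change of the difference did not pass (-0.38, adjusted p = 0.825), with a spread widened by the library labelled P7.5 KO replicate 2.

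By camera 9 lists passed, 7 down and 2 up, and 0 with an estimated correlation. Hepatocyte secreted proteins had 9 of 28 genes down (adjusted p = 0.00255, and adjusted p = 0.791 with an estimated correlation). Glycolysis had 6 of 17 down (7 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.753 with an estimated correlation). Glycogen metabolism had 8 of 16 down (9 adjusted over the list alone, adjusted p = 0.0206, and adjusted p = 0.681 with an estimated correlation). Fatty acid oxidation had 9 of 23 down (adjusted p = 0.0206, and adjusted p = 0.791 with an estimated correlation). The insulin and growth factor axis had 6 of 14 down (adjusted p = 0.0206, and adjusted p = 0.681 with an estimated correlation). Amino acid catabolism had 8 of 48 down (adjusted p = 0.0273, and adjusted p = 0.791 with an estimated correlation). Stellate cell and fibroblast genes had 5 of 17 down (7 adjusted over the list alone, adjusted p = 0.0346, and adjusted p = 0.791 with an estimated correlation). Up were ribosomal proteins, with 6 of 40 up and 1 down (adjusted p = 0.0346, and adjusted p = 0.681 with an estimated correlation). B lymphoid genes were up too, with 2 of 15 up (adjusted p = 0.0408, and adjusted p = 0.791 with an estimated correlation).

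From P2.5 to P7.5 the genotype difference moved up for stellate cell and fibroblast genes, and an effect of single KO slides cannot be told apart from this either. Fn1 changed by 3.13, Nid1 by 3.14, Ptprb by 3.19, Dcn by 1.98 ± 0.25 (SE, log2, limma adjusted p = 3.09e-05) and Col1a2 by 1.75, with Atp2b2 at 3.54 and Eif4ebp2 at 3.12. It moved down for Mt2 (-3.29, adjusted p = 0.0425), Prg2 (-3.01), Rnu1b6 (-2.62), Mmd2 (-2.52), Gdpd2 (-2.35), Rps27 (-0.97) and Rps3 (-0.75). Without the library labelled P7.5 KO replicate 2 the change of Mt2 was -4.53 (adjusted p = 0.000393). In all 5323 genes passed, 2669 up and 2654 down, and 4953 with slide as a random block. By camera 2 lists passed with all libraries. They were stellate cell and fibroblast genes with 12 of 17 up and 0 down (13 and 1 adjusted over the list alone, median 1.07, adjusted p = 5.11e-05, and adjusted p = 0.74 with an estimated correlation) and ribosomal proteins with 16 of 40 down and 2 up (19 and 2 adjusted over the list alone, adjusted p = 0.00427, and adjusted p = 0.593 with an estimated correlation). Without the library labelled P7.5 KO replicate 2 there were 8 lists, each at adjusted p = 0.473 or above with an estimated correlation. The 6 lists added were fatty acid oxidation (10 of 23 up, adjusted p = 0.00797), lipogenesis (5 of 14 up), cholesterol synthesis (6 of 24 up and 1 down) and the insulin and growth factor axis (6 of 14 up, each of these 3 at adjusted p = 0.0213), endothelial genes (6 of 17 up and 1 down, adjusted p = 0.0334) and T and NK lymphoid genes (5 of 15 down, adjusted p = 0.00608). For Gcgr the change was 1.25 (adjusted p = 0.333) with the library labelled P7.5 KO replicate 2 and 0.02 (adjusted p = 0.957) without it.

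How WT liver changes around birth was read from E18.5 to P2.5. Fatty acid oxidation genes rose, with Acadvl and Acadl. So did the apolipoprotein gene Apoa4, the sulfotransferase genes Sult2a4, Sult2a1, Sult2a2 and Sult1c2, and the cytochrome P450 genes Cyp1a2 and Cyp2b10. The complement genes C3 and C8a and the amino acid breakdown genes Gldc and Bckdhb were higher at P2.5. The growth factor genes Igf1 and Igfbp2 and the respiratory chain genes Uqcrq and Ndufv1 rose too. Genes of lipid synthesis fell, with Scd1, Scd2, Fasn, Insig1 and Mvd, and so did the glycolytic genes Hk1 and Pgam1, the retinol-binding gene Rbp2 and Hkdc1. Erythroid, granulocyte and some B cell genes fell, among them the erythroid genes Bpgm and Nfe2, the granulocyte genes Retnlg and Mmp8, Ear6 and the early B cell gene Igll1, while the B cell gene Ms4a1 rose. The mean of the megakaryocyte list in WT was 3.09 at E18.5 and 3.12 at P2.5.

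Apoa4 rose by 5.10 ± 0.35 on the log2 scale (SE, n = 4 against 4, limma adjusted p = 9.03e-10). Sult2a4 rose by 3.86, Sult2a1 by 3.62, Sult1c2 by 3.60, Sult2a2 by 3.53, Cyp1a2 by 2.94 and Cyp2b10 by 2.02. Acadvl rose by 1.55 ± 0.11 (adjusted p = 1.5e-09). Acadl rose by 1.37, C3 by 1.57, C8a by 1.38, Ms4a1 by 1.54, Igfbp2 by 1.23, Gldc by 1.06, Bckdhb by 0.99, Uqcrq by 0.89, Igf1 by 0.82 and Ndufv1 by 0.46. Scd2 fell by 3.59 ± 0.22 (adjusted p = 3.72e-10). Scd1 fell by 3.18, Ear6 by 3.28, Rbp2 by 3.28, Hkdc1 by 2.93, Insig1 by 2.29, Fasn by 1.27, Mvd by 1.23, Pgam1 by 1.19 and Hk1 by 0.73. Retnlg fell by 2.08, Mmp8 by 1.97, Igll1 by 1.83, Bpgm by 1.59, Nfe2 by 1.24, the cell cycle genes Nusap1 and Ube2c by 0.82 and 0.57, and Rps3 and Rps2 by 0.45 and 0.35. In all 5354 genes passed, 3104 higher and 2250 lower at P2.5, and 687 changed at least 2-fold, 375 higher and 312 lower. The split was 2413 higher and 2451 lower with the log ratios of Feature Extraction and 2489 higher and 2497 lower in Cy5 alone. With slide as a fixed block over the 12 WT libraries 3902 passed. Slides 1, 2 and 3 each held both ages. Of the genes called without the libraries of the slide, 96.2%, 86.8% and 90.4% had the same sign within it.

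Of the fatty acid oxidation genes 18 of 23 rose and 0 fell (20 adjusted over the list alone, median 1.03, camera adjusted p = 6.19e-13, and adjusted p = 0.115 with an estimated correlation). Within the 3 slides its median was 0.79, 1.33 and 0.89. Lipogenesis had 10 of 14 genes lower and 1 higher (the same adjusted over the list alone, camera adjusted p = 2.63e-06, and adjusted p = 0.115 with an estimated correlation). Cholesterol synthesis had 11 of 24 lower and 1 higher (12 and 2 adjusted over the list alone, camera adjusted p = 0.000188, and adjusted p = 0.531 with an estimated correlation). Granulocyte and monocyte genes had 14 of 18 lower (16 adjusted over the list alone, camera adjusted p = 4.71e-08, and adjusted p = 0.513 with an estimated correlation). Erythroid genes had 19 of 29 lower and 2 higher (22 and 3 adjusted over the list alone, camera adjusted p = 1.52e-07, and adjusted p = 0.513 with an estimated correlation). Drug metabolizing enzymes had 13 of 25 higher and 2 lower (14 and 2 adjusted over the list alone, camera adjusted p = 0.000163, and adjusted p = 0.526 with an estimated correlation). Amino acid catabolism had 19 of 48 higher (19 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000188, and adjusted p = 0.531 with an estimated correlation). The other lists among the 15 that passed were higher for oxidative phosphorylation (adjusted p = 0.0046), hepatocyte secreted proteins (0.0106), the insulin and growth factor axis (0.0171) and bile acid synthesis and transport (0.0462). They were lower for B lymphoid genes (0.0046), ribosomal proteins (0.00856), cell cycle (0.0106) and glycolysis (0.033), whose median was -0.17 and -0.22 within slides 1 and 3 but 0.21 within slide 2. With an estimated correlation camera left 0 of the 34 lists.

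From P2.5 to P7.5 genes of cell division and of red cells and megakaryocytes fell in WT liver, while genes of the respiratory chain, amino acid breakdown, T cells and the acute phase rose. The proliferation genes Mki67 and Ccna2, the erythroid genes Ermap and Epor, the platelet genes Itga2b and Vwf, the fetal genes Lin28b and Dlk1 and the amino acid transporter genes Slc38a5 and Slc1a5 fell. The water channel gene Aqp3, Igsf1, Ggt1, Rgs16 and Apoa4 fell too. The acute phase genes Saa1, Saa2, Saa3 and Orm2 rose. So did the methyltransferase gene Inmt, the organic anion transporter gene Slc22a7, the T cell genes Cd3d and Cd3g, the respiratory chain genes Sdhb and Ndufs3 and the amino acid breakdown genes Bckdhb and Amt.

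Saa2 rose by 5.50 ± 0.76 on the log2 scale (SE, n = 4 against 4, limma adjusted p = 1.25e-05). Inmt rose by 4.33, Orm2 by 3.44, Saa1 by 3.38, Slc22a7 by 3.08, Cd3d by 2.53, Saa3 by 2.13, Cd3g by 1.05, Sdhb by 0.94, Bckdhb by 0.77, Ndufs3 by 0.69 and Amt by 0.69. Aqp3 fell by 3.46 ± 0.25 (adjusted p = 3.3e-09). Igsf1 fell by 3.18, Rgs16 by 3.06, Apoa4 by 2.74, Ggt1 by 2.72, Dlk1 by 2.46 and Ermap by 2.41. Lin28b fell by 2.15, Slc38a5 by 2.07, Itga2b by 1.97, Mki67 by 1.96, Epor by 1.46, Vwf by 1.26, Ccna2 by 0.99 and Slc1a5 by 0.80. In all 6441 genes passed, 3595 higher and 2846 lower at P7.5, and 600 changed at least 2-fold, 291 higher and 309 lower. In Cy5 alone the split was 2789 higher and 2989 lower. With slide as a fixed block 5116 passed. Within slides 1, 2 and 5 the sign was the same for 98.7%, 87.6% and 95.3% of the genes called without the libraries of the slide.

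The cell cycle list had 27 of 36 genes lower and 1 higher (28 and 1 adjusted over the list alone, camera adjusted p = 8.88e-11, and adjusted p = 0.54 with an estimated correlation). Its median was -0.48, -0.26 and -0.56 within the 3 slides. Erythroid genes had 21 of 29 lower and 1 higher (22 and 2 adjusted over the list alone, median -1.27, camera adjusted p = 3.46e-09, and adjusted p = 0.54 with an estimated correlation). Megakaryocyte genes had 10 of 14 lower and 1 higher (12 and 1 adjusted over the list alone, camera adjusted p = 3.3e-06, and adjusted p = 0.54 with an estimated correlation). Oxidative phosphorylation had 16 of 31 higher (17 adjusted over the list alone, camera adjusted p = 3.57e-05, and adjusted p = 0.54 with an estimated correlation). The T and NK lymphoid list had 9 of 15 higher (9 adjusted over the list alone, camera adjusted p = 0.000379, and adjusted p = 0.54 with an estimated correlation). Amino acid catabolism had 24 of 48 higher and 3 lower (28 and 3 adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.639 with an estimated correlation). Amino acid transporters (9 of 21 lower, adjusted p = 0.00731), fetal liver genes (7 of 18 lower, adjusted p = 0.0136) and acute phase genes (8 of 15 higher, adjusted p = 0.0235) made up the 9 lists. With an estimated correlation camera left 0 of them.

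In KO liver the changes with age were measured on slides that each held 1 age, so that age and slide cannot be told apart there. From E18.5 to P2.5 the sulfotransferase genes Sult2a4, Sult2a1, Sult2a2 and Sult2a6 rose by 5.48, 4.9, 4.60 and 4.42, and Apoa4 by 4.26 ± 0.35 (SE, n = 4 against 4, limma adjusted p = 8.3e-09). Hkdc1 fell by 4.34, A2m by 4.24, Scd2 by 4.18, Serpina4-ps1 by 3.83 and Rbp2 by 3.50. In all 5844 genes passed, 2766 higher and 3078 lower at P2.5, and 5045 with slide as a random block. From P2.5 to P7.5 Prg4 rose by 3.32 ± 0.17 (adjusted p = 1.29e-11). Slc22a7 rose by 3.06, Cyp4f14 by 2.95, Inmt by 2.84 and the pancreatic lipase relative Pnliprp1 by 2.44. Aqp3 fell by 3.65, the protein disulfide isomerase gene Pdia2 by 3.45, the blood cell transcription factor gene Gfi1b by 2.87, Rgcc by 2.75 and the sphingosine kinase gene Sphk1 by 2.68. These directions held without the library labelled P7.5 KO replicate 2, with Prg4 at 3.14 and Aqp3 at -3.39. In all 6483 genes passed, 3713 higher and 2770 lower at P7.5. The split was 3436 higher and 3859 lower in Cy5 alone and 2826 higher and 3148 lower with the log ratios of Feature Extraction, and 5628 passed with slide as a random block. Gcgr did not pass between ages in KO (0.20, adjusted p = 0.853, and 1.04, adjusted p = 0.234, with the library labelled P7.5 KO replicate 2). That library widened the spread of Gcgr in both comparisons.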

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

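The tests of a slide offset and of receptor loss for the changes shared by E18.5 and P7.5, of exchanged labels and of an intact-Gcgr liver for the library labelled P7.5 KO replicate 2, of other libraries left out in turn, of list positions, of sex, and of Epx for the eosinophil genes were chosen only after the result was seen.

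The KO-WT differences shared by E18.5 and P7.5 cover 2850 genes called the same way at E18.5 and at P7.5 without the library labelled P7.5 KO replicate 2, of which 631 were called the same way at P2.5 and 242 the opposite way. A difference in the Cy3 reference between slide sets is argued against as the main source, since the Cy5 change over the log ratio change had a median of 0.85 (quartiles 0.532 and 1.15) and 93.4% of the genes moved the same way in Cy5. An offset of the KO slides and loss of the receptor both stay open: the library labelled P7.5 KO replicate 2, on a KO slide but with Gcgr present, lay at a median position of 0.732 (quartiles 0.521 and 0.952) between WT (0) and the other KO libraries (1). P7.5 KO replicate 1, with Gcgr at 0.00, lay at 0.801 when left out together with the library labelled P7.5 KO replicate 2. That position was scaled to the remaining KO libraries over 2667 genes called anew, so 0.732 and 0.801 are on unlike scales. The position of 1 library between the groups does not tell the explanations apart for these genes.

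Gcgr stood at 5.02 in the library labelled P7.5 KO replicate 2, above the other KO libraries (-0.01 to 0.38). It lay within the range of WT libraries of all ages (4.87 to 6.26) but below the P7.5 WT libraries (5.50 to 5.65). An exchange with a WT library of the series is argued against, since 0 WT libraries lay below the midpoint of 2.85. WT RNA mixed into a KO library would keep genes that are high in KO at the level its remaining KO RNA gives, but the 3 genes that could test this differed from that level by a median of -1.65 (SD 1.22), which argues against a mixture as far as 3 genes can. A liver with intact Gcgr under a KO label may be the source. Over 2762 genes called at P7.5 alone the library lay at a median position of 0.444 (quartiles 0.108 and 0.788). P7.5 KO replicate 1, left out together with it, lay at 0.514, and replicates 3 and 4 likewise at 1.08 and 1.06. Those positions were scaled to the remaining KO libraries without replicate 2, over genes called anew, so 0.444 and 0.514 are on unlike scales. This position alone does not single the library out. By list means it lay near WT for amino acid catabolism (0.0640), urea cycle (-0.199), acute phase (-0.00607), megakaryocyte (-0.157) and T and NK lymphoid genes (-0.146), where P7.5 KO replicate 1 lay apart from it (3.03 against 3.68, 3.62 against 4.57, 3.54 against 4.10, 1.44 against 2.41 and 0.96 against 1.38), but with the KO libraries for ribosomal proteins (0.936). It lay between the groups for endothelial (0.224), stellate cell and fibroblast (0.324), hepatocyte secreted (0.573) and oxidative phosphorylation genes (0.599). It was also the only library of its group with Ddx3y below the reference (-2.56), and although sex moved the genes called at P7.5 alone in P7.5 WT by a median of -0.0537 of the KO change, sex is not separated from its position.

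Eosinophil granule genes were low in the P2.5 WT libraries. Fewer granulocytes and monocytes of all kinds would need their list to rise by a median of at least 1 in KO against WT at P2.5. The list changed by 0.22, with 2 standard errors over its genes of 0.253, which argues against this as far as the genes of the list go. That bound does not cover the spread between libraries, where the list mean had an SD of 0.67 in P2.5 WT and 0.12 in P2.5 KO. An offset of the slides is argued against, since within slides Prg2 was at least 2.01 higher at another age than at P2.5. Signal shared between related probes is argued against, since Epx, which is not related in sequence to Prg2, changed by 1.92. A difference in eosinophils themselves between the P2.5 WT livers and the others may stay as a hypothesis, and no test of it was made.

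Single libraries stood apart from the other 3 of their group in 31 of 523 pairs of a gene and a group, where chance, which marks about 1 in 20 groups, would give 26.15. In 5 of these pairs the library labelled P7.5 KO replicate 2 stood apart, with Gcgr at 5.02, Gp9 at 3.48, Rgs16 at -0.52, Sdsl at 1.68 and Prg4 at 4.36. E18.5 WT replicate 2 stood apart for Acadvl (1.38), Ldha (-0.17), Rprl2 (2.87), Slc7a8 (1.07), C3 (2.91), Scd1 (0.74) and Nid1 (-1.63). E18.5 KO replicate 1 did so for Cd79b (0.31), and E18.5 KO replicate 4 for Epx (2.20). At P2.5 the libraries were WT replicate 1 for Fasn (-0.082), WT replicate 2 for Bckdhb (2.16) and Lin28b (2.29), WT replicate 3 for Cyp2b10 (4.13), WT replicate 4 for Saa1 (-0.29), KO replicate 3 for Acads (1.40) and F9 (2.49), and KO replicate 4 for Sik1 (2.05), Plagl1 (2.56), Reln (0.99) and Dcn (0.77). At P7.5 they were WT replicate 4 for Fgl1 (8.68), Jun (-2.68) and Rbp4 (8.89), WT replicate 1 for Timp2 (-3.94), WT replicate 3 for Gdpd2 (-0.999) and KO replicate 1 for Pdia2 (0.95). E18.5 WT replicate 2, P2.5 WT replicate 3 and P7.5 WT replicate 4 lay on slide 2, and an effect of that slide was not tested.

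The KO-WT difference changed between ages by the interaction test. From E18.5 to P2.5 it did so for 3473 genes and 9 lists, and from P2.5 to P7.5, with the library labelled P7.5 KO replicate 2, for 5323 genes and 2 lists. With an estimated correlation in camera 0 lists passed in either, and 25 and 97 of 100 splits gave as many lists. From E18.5 to P2.5 the log2 changes of the difference were -2.79 for A2m, -0.87 for Acads, -1.05 for Acadvl, -0.78 for Aldoa, -2.26 for C3, 1.19 for Cd79b, 3.62 for Ear6, and -1.23 for Ecm1. They were 2.89 for Epx, -1.41 for F9, -3.12 for Fn1, -0.82 for Gapdh, -0.84 for Hibadh, -1.80 for Igfbp1, and -1.43 for Insr. They were -2.35 for Itih5, -0.60 for Mccc1, -2.39 for Nid1, 3.61 for Obox1, -0.63 for Phka2, and -2.30 for Plagl1. They were 3.09 for Prg2, 2.93 for Prg3, -1.29 for Reln, 0.67 for Rps27, 0.49 for Rps3 and 1.29 for Vpreb3. F9 and Igfbp1 turned sign in Cy5 alone. From P2.5 to P7.5 they were 3.54 for Atp2b2, 1.75 for Col1a2, 1.98 for Dcn, 3.12 for Eif4ebp2, 3.13 for Fn1, and -2.35 for Gdpd2. They were -2.52 for Mmd2, -3.29 for Mt2, 3.14 for Nid1, -3.01 for Prg2, 3.19 for Ptprb, -2.62 for Rnu1b6, -0.97 for Rps27 and -0.75 for Rps3.

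The Cy3 channel, which held the same kind of reference on every array, differed between KO and WT arrays at 7567 genes at E18.5, 6894 at P2.5 and 7928 at P7.5, of which 94, 79 and 79 differed at least 2-fold. These were 43.8%, 39.9% and 45.9% of the genes tested. In the log ratio 27.1%, 24.1% and 35.5% passed for KO against WT. Across genes the Cy3 change correlated with the log ratio change at -0.132, -0.0216 and -0.215.

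Other splits of the same 8 libraries into groups of 4 were compared with the real one for each count. For genes the real split alone gave as many, 1 of 35 splits each, the smallest share that 35 splits can give. It did so at E18.5 (4680, highest other 7), P2.5 (4166, highest other 3252), P7.5 with the library labelled P7.5 KO replicate 2 (6126, highest other 471), between ages in WT (5354, highest other 1691, and 6441, highest other 2) and in KO (5844, highest other 700, and 6483, highest other 2305). KO and WT, and the ages in KO, lay on separate slides, so an effect of slides would also put the real split first. For the interactions 1 of 100 splits drawn gave as many (3473, highest other 789, and 5323, highest other 2945). The highest other split at P2.5 set WT replicates 1, 2 and 4 with KO replicate 4 against the rest. WT replicate 3, which fell with the other KO libraries, was the only P2.5 WT library on slide 2. KO replicate 4 shared slide 7 with KO replicates 1 and 2. On slide 2, P2.5 WT replicate 3 and E18.5 WT replicate 2 had array weights of 0.244 and 0.248, but P7.5 WT replicate 4 had 1.67. An effect of slide 2 was not tested. For lists chance cannot be excluded: 22 of 35 splits gave as many at P2.5 (6, highest other 14), 24 at P7.5 (8, highest other 16), 5 and 18 between ages in WT (15, highest other 16, and 9, highest other 20), and 25 and 97 of 100 for the interactions (9, highest other 17, and 2, highest other 21). At E18.5 0 lists passed (highest other 8), so 35 of 35 splits had to give as many and the comparison could not decide.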

How the results depend on the processing

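Background fitted on all spots, slide as a fixed block for the list counts, omission of single libraries for the list counts, and omission of both libraries in doubt were chosen only after the result was seen. Of the values compared under other settings 12368 kept their direction and their side of the threshold, 261 lost the threshold, 225 gained it, 69 counts moved and 14 changed sign. Those that kept them include the quantile normalization of average intensities (265 values of named genes and 238 of single lists, besides counts), which could not differ. The cause was not tested for any of these unless stated. Genes near background limit what arrays can show.

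Among values that passed in at least 1 of the settings compared, signs turned under 2 settings. In the Feature Extraction log ratio Hkdc1 was -0.19 at E18.5, Igf2 0.054 at P2.5 and the endothelial list -0.086 at P7.5. In Cy5 alone Ppargc1a was -0.34 and Rpl4 -0.079 at E18.5, Fgg 0.22, Nr4a2 -0.016 and Rbp4 0.18 at P2.5, Fgg 0.080, Fgl1 0.20, Rbp4 0.043 and the hepatocyte secreted list 0.025 at P7.5, and F9 0.17 and Igfbp1 0.66 for the change of the difference from E18.5 to P2.5.

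Counts of genes changed moved by over 1.5 times under array weights (KO vs WT at P7.5 9936, KO-WT difference at P7.5 vs P2.5 8220) and in fits on only the arrays of the groups compared (KO vs WT at P2.5 1694, WT P2.5 vs E18.5 3053). Counts of genes changed at least 2-fold moved by over 1.5 times in all 9 comparisons with the Feature Extraction log ratio (1106, 1011 and 1402 for KO vs WT, 1062 and 1118 between ages in WT, 1342 and 1386 in KO, 919 and 1628 for the changes of the difference). They moved also in Cy5 alone (321 at E18.5, 334 at P2.5), with the mean of all probes (130 at E18.5), with array weights (698 at P7.5, 1500 for the change from P2.5 to P7.5), without E18.5 WT replicate 2 (311 for the change from E18.5 to P2.5), without the library labelled P7.5 KO replicate 2 (562 at P7.5) and without both libraries in doubt (572 at P7.5). Counts of lists moved too. For KO vs WT at E18.5 there was 1 with the mean of all probes. For KO vs WT at P2.5 there were 1 with the Feature Extraction log ratio, 10 with no filter, 12 with the compared groups alone and 3 with normexp fitted on all spots. For KO vs WT at P7.5 there were 5 in Cy5 alone, 4 with the compared groups alone and 2 with normexp fitted on all spots. For WT P7.5 vs P2.5 there were 14 with array weights and 16 with slide as a fixed block (17 for WT P2.5 vs E18.5). For the KO-WT difference at P2.5 vs E18.5 there were 0 with the Feature Extraction log ratio, 2 with array weights and 14 with the compared groups alone. For the KO-WT difference at P7.5 vs P2.5 there were 6 with no background subtraction, 8 in Cy5 alone, 6 with no filter, 7 with the mean of all probes, 9 with array weights, 5 with the compared groups alone and 10 without both libraries in doubt. With an estimated correlation in camera 0 lists passed in every comparison. The stellate cell and fibroblast list at P7.5 passed in every other setting.

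With 1 library left out in turn the counts of genes changed ranged from 3626 to 4743 at E18.5, 2912 to 4794 at P2.5, 4729 to 6500 at P7.5, 4674 to 5482 and 5510 to 6509 between ages in WT, 4805 to 6368 and 5531 to 6742 in KO, and 2512 to 4317 and 4295 to 6050 for the changes of the difference. Counts of lists ranged from 0 to 1 at E18.5, 2 to 10 at P2.5, 5 to 10 at P7.5, 11 to 16 and 9 to 12 between ages in WT, and 5 to 15 and 2 to 9 for the changes of the difference. Libraries whose omission moved a list count by over 1.5 times were E18.5 WT replicate 2 at E18.5 (1), P2.5 WT replicate 1 (10) and P2.5 KO replicates 1 (10), 3 (2) and 4 (3) at P2.5, and P7.5 KO replicates 1 (5) and 4 (5) at P7.5. For the change from E18.5 to P2.5 they were E18.5 WT replicate 4 (5), P2.5 WT replicate 3 (5), E18.5 KO replicate 1 (14) and P2.5 KO replicates 1 (15) and 2 (14). For the change from P2.5 to P7.5 they were P2.5 WT replicates 1 (9), 2 (4) and 4 (5), P7.5 WT replicates 1 (5) and 4 (6), P2.5 KO replicates 1 (6) and 2 (6), P7.5 KO replicate 1 (4) and the library labelled P7.5 KO replicate 2 (8).

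The replicate numbers showed no general pairing of the libraries: the deviations of same-numbered libraries correlated between -0.575 and 0.427. Between P2.5 and P7.5 in WT, numbers 1, 3 and 4 correlated at 0.116, 0.120 and 0.218, each best with its own number, and number 2 at -0.037. With the replicate block the counts of genes changed were 4725, 4266 and 6167 for KO against WT, 5383, 6469, 5873 and 6511 between ages, and 3541 and 5404 for the changes of the difference, and lists were 0, 7, 8, 15, 9, 8 and 5.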

Other observations

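The test of the small structured RNAs and the positions of other libraries left out in the same way were chosen only after the result was seen, and those of the scan day and of the genes near Gcgr were not.

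Within the P2.5 KO group replicate 3 lay on another slide and was scanned on another day than the rest. If the scan day of the other KO libraries made the KO-WT differences at P2.5, this library would lie near WT. Over the 3102 genes called without it, its median position between WT (0) and the other KO libraries (1) was 1.03 (quartiles 0.684 and 1.35). KO replicates 1, 2 and 4, left out in the same way, lay at 1.03, 0.928 and 0.534. Replicate 3 lay with the other KO libraries, but it shares with them the separate set of KO slides, so that the slide set cannot be told apart from genotype.

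DNA of the embryonic stem cell strain often stays around a deleted gene and can change its neighbours in every KO sample. Among the 100 genes around Gcgr 2 changed the same way at all 3 ages, against a median of 3 and a highest number of 10 in other stretches of 100 genes, and 88.2% of stretches held as many. By this count the test was negative. The 2 genes were Nploc4 (-0.22, -0.30 and -0.22 at E18.5, P2.5 and P7.5) and Aspscr1 (-0.31, -0.32 and -0.24). A count over 100 genes cannot exclude an effect on a few neighbours of Gcgr. The P7.5 calls included the library labelled P7.5 KO replicate 2.

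Of 12 genes for small structured RNAs 8 were lower and 0 higher in KO at E18.5 (median -0.62), and 9 were lower and 0 higher at P7.5 with the library labelled P7.5 KO replicate 2 (median -0.93), while at P2.5 0 were called lower and 2 higher (median 0.11). Rprl2 and Rpph1 changed by -1.135 and -0.71 at P2.5 without passing, while Rnu2-10 changed by 0.98. Between P7.5 WT (0) and the other P7.5 KO libraries (1) the library labelled P7.5 KO replicate 2, with Gcgr present, was placed for the genes that fell. It lay at 0.974 for Rnu1b6, 1.19 for Rmrp, 0.933 for Rpph1, 1.15 for Rnu2-10 and 0.811 for Rprl2. For Rnu12, Rnu3b1, Rnu7 and Terc it lay at 0.856, 0.785, 1.13 and 1.18. Snora74a, Snora47 and Snord123 were not called lower. Their changes at P7.5 were -0.13, -0.053 and 0.18, too small for a position to be read. This library alone does not decide whether the falls follow Gcgr. RNA preparation was not tested as a source.

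Ddx3y, which lies on the Y chromosome, was above the reference in 15 libraries and below it in 9, so that livers of both sexes were present, with 1, 3 and 2 of 4 above it in WT at E18.5, P2.5 and P7.5 and 2, 4 and 3 of 4 in KO.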
